A study of Xenopus tropicalis with 24 samples.

How the data were processed

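RNA was extracted from intestine and tail of stage 54 Xenopus tropicalis with a column kit, and libraries were made from 1 µg of RNA with a stranded total RNA kit, per the labels' protocols. Adapters were trimmed with cutadapt 3.2, reads aligned with STAR 2.7.7a and genes counted with featureCounts of Subread 2.0.1, per the submitters' processing notes. The deposited values are whole-number counts of fragments per gene, not normalized, for 26531 genes in 24 libraries. Per the file headers, counting was reverse-stranded, kept read pairs with both ends mapped and not chimeric, took primary alignments only, dropped reads marked as duplicates and grouped an XENTR_10.0 annotation by gene name. A read that maps to several copies of a gene is therefore counted at its primary alignment, which can move reads between paralogs, and dropping duplicates without molecular identifiers can lower the values of the most abundant genes. Of the gene symbols 26530 matched a reference table of assembly UCB_Xtro_10.0, and 10633 were provisional locus symbols. Mitochondrial genes were not analysed here.

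Library totals ranged from 17577407 to 24699154 fragments. Replicates were compared by a chi-square test over genes with at least 20 counts. Tail WT control replicates 1 and 3 did not differ beyond sampling noise (mean chi-square 1.014, p = 0.1057 by the chi-square test over genes) and were summed and counted as 1 sample, which left 11 tail and 23 samples in all. Genes were filtered with edgeR's filterByExpr by group, leaving 15491 genes in intestine, 17018 in tail and 17887 in the fit over both organs. Counts were scaled by trimmed means of M values (TMM) and tested with edgeR 4.0.16's robust quasi-likelihood F test in R 4.3.3. The fit had 1 coefficient per group and edgeR's default prior count, and a prior count of 2 was used only for log CPM values compared between libraries. The p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast at a threshold of 0.05. Contrasts were T3 against control in each genotype, TRDKO against WT control, the genotype by T3 interaction in each organ, and the tissue by T3 interaction in each genotype. Their tests, the gene lists and all alternatives except those named last were fixed before the data were examined. Summing tail WT control replicates was decided on these data.

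The text names thra, thrb and the members of the list of known thyroid hormone response genes, the 10 largest rises and 10 largest falls per contrast among genes that passed with a mean of at least 5 CPM in the higher group, no overlap of the groups (except in interactions) and a gene name as symbol, and up to 4 members of a list, the largest rises and falls that passed. For 3 libraries against 3, groups that do not overlap in a given direction and its opposite arise in 10% of genes by chance. Folds against a group with no count use a floor of 3 counts over the group and are lower bounds, and with 1 to 3 counts the ratio is given with its exact 95% counting interval. A list median is also given with every group of its members held at no less than that floor.

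The 39 lists were thyroid hormone receptors and RXR partners, known thyroid hormone response genes, thyroid hormone metabolism and transport, nuclear receptor coregulators, corticosteroid response, matrix proteases and inhibitors, collagens and matrix proteins, DNA replication, mitosis, apoptosis, lysosome and autophagy, proteasome and ubiquitin ligases of muscle, intestinal stem cell, WNT signalling, Hedgehog and BMP signalling, Notch signalling, MAPK feedback and immediate early genes, unfolded protein response, heat shock and oxidative stress, cholesterol synthesis, fatty acid oxidation and lipid synthesis, glycolysis and gluconeogenesis, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis, interferon response, larval enterocyte, intestinal secretory and endocrine, exocrine pancreas, hepatocyte, skeletal muscle, smooth muscle, notochord and cartilage, epidermis, nerve and glia, macrophages and granulocytes, lymphocytes, erythrocytes and endothelium. Each was tested with limma 3.58.1's camera on voom values with a preset inter-gene correlation of 0.01, for lists with at least 5 measured members, adjusted by the Benjamini-Hochberg method over lists and contrasts of 1 organ, and again with an estimated correlation. The estimated correlation kept 4, 7, 5 and 7 of the list calls in intestine (T3 in WT, T3 in TRDKO, TRDKO against WT, interaction), 6, 16, 9 and 10 in tail, and 5 and 7 in the organ tests of WT and TRDKO. Members were also tested with p-values adjusted over the list alone. Overlaps of calls were tested with Fisher's exact test (2-sided) beside the product of the list sizes over the genes tested in both, and contrasts that share control libraries were set beside 20 simulations of unchanged groups.

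The pipeline was tested on simulated counts with genes changed by 1.2, 1.5, 2 and 4-fold. It recovered 14%, 76%, 92% and 96% of them for T3 in WT intestine and 42%, 82%, 92% and 98% for T3 in WT tail. For the genotype by T3 interaction it recovered 4%, 48%, 78% and 94% in intestine and 34%, 64%, 84% and 94% in tail. Alternatives were DESeq2 size factors, upper-quartile scaling, no or a stricter count filter (5 CPM in 3 libraries), a 2-fold minimum, DESeq2 1.42.0, limma-voom, the replicate number as a block, the 50 most abundant genes left out, all libraries in 1 fit, only the libraries compared, and each library left out in turn (a lone tail WT control sample is then assumed to vary like the other groups). Keeping the tail WT control libraries apart, and leaving out intestine TRDKO T3 replicate 3 for lists and overlaps, were chosen after seeing the data.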

Results

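Messenger RNA abundance was measured in intestine and tail of Xenopus tropicalis tadpoles at stage 54, before the natural surge of thyroid hormone. Wild-type (WT) animals and animals labelled TRDKO, a double knockout of the thyroid hormone receptors, were kept without hormone (control) or with 5 nM T3, the active thyroid hormone, for 18 h at 25 °C. Each of the 8 groups held 3 libraries, 24 in all. Genes with a count ranged from 17918 to 19655 per library, and the share of the 10 most abundant genes from 5.00% to 6.75%. Tail WT control replicates 1 and 3 were counted as 1 sample, so n = 2 there and n = 3 elsewhere. Log2 fold changes are given ± a standard error, which is too small where a group has few counts. CPM, counts scaled by trimmed means to a common library total, are means ± SD over these samples. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. That spread was small, with a biological coefficient of variation of 6.28% in intestine and 1.68% in tail, so small changes passed the test. Intervals and floors cover counting error only.

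The receptor genes were read first in every library. In assembly UCB_Xtro_10.0, thra lies on chromosome 10 from 9063035 to 9190651 and thrb on chromosome 6 from 46687270 to 46933187, both on the minus strand, and thibz, a transcription factor gene induced by thyroid hormone, on chromosome 3 from 140193605 to 140202878 on the plus strand. In intestine, thra stood at 8.54, 10.6 and 11.2 CPM in WT control (values per library of these genes were scaled over all 24 libraries, and their group means within each organ), 7.096, 7.67 and 9.23 in WT T3, 5.13, 5.54 and 4.98 in TRDKO control and 12.7, 14.95 and 3.74 in TRDKO T3. The thrb values were 3.49, 3.503 and 3.42, then 67.3, 66.8 and 67.7, then 4.93, 5.59 and 4.98, then 38.6, 42.5 and 28.5 CPM in the same order. Tail thra was 7.702, 8.62 and 8.19, then 4.602, 4.795 and 3.63, then 8.398, 6.41 and 6.98, then 9.37, 10.8 and 8.77 CPM. Tail thrb was 6.57, 6.26 and 7.66, then 51.6, 53.6 and 50.8, then 26.6, 24.2 and 25.6, then 47.2, 46.9 and 49.3 CPM. Transcripts of both receptors were thus counted in every library labelled TRDKO. The labels do not give the lesions, and a small deletion leaves the transcript countable, so these counts do not check the genotype labels.

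Intestine TRDKO T3 replicate 3 stood apart from its group, with thra at 3.74 CPM against 12.7 and 14.95 in the other two libraries and mean chi-square values of 25.7 and 32.8 against them, where no other pair of one group exceeded 2.90. Values on this group include that library, and counts of genes, lists and overlaps, with klf9 and thra, are also given without it, which for lists and overlaps was chosen after seeing the data. Of the list of thyroid hormone receptors and RXR partners, 2 of 5 measured members rose, 1 fell and 2 did not pass with T3 in WT intestine, and in WT tail 2 of 5 measured members rose, 3 fell and 0 did not pass. Thyroid hormone receptors and RXR partners calls adjusted over the list alone numbered 3, with a median log2 fold change of 0.24 (camera adjusted p = 0.273). Thyroid hormone receptors and RXR partners had 5 calls adjusted over the list alone and a median log2 fold change of -0.54, a mean of 0.22 and a camera direction down (camera adjusted p = 0.983).

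**Figure D1:**
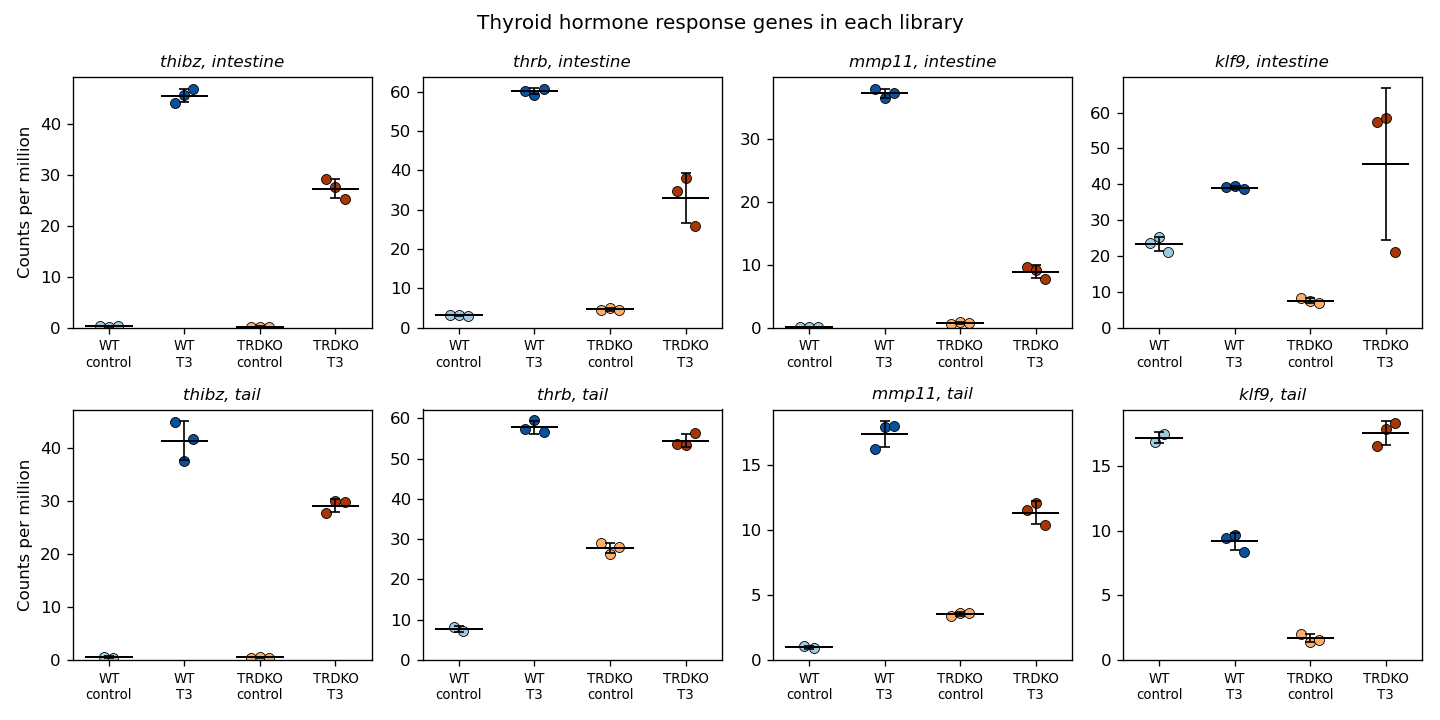
Levels of thibz, thrb, mmp11 and klf9 in CPM (vertical axes, from 0) for each library (points) with group mean and SD (lines), by genotype and treatment, intestine above and tail below. Mean thibz was 0.238 CPM in WT control, 45.5 in WT T3, 0.174 in TRDKO control and 27.3 in TRDKO T3 intestine.

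The first comparison asked how T3 changed the WT intestine. The hormone raised thrb, a receptor gene that thyroid hormone itself induces, by 4.27 ± 0.13 on the log2 scale (60.05 ± 0.775 against 3.12 ± 0.0555 CPM), and mmp11, a matrix metalloproteinase of remodelling tissue, by 9.13 ± 0.19 (37.2 ± 0.726 against 0.06003 ± 0.0215 CPM). Genes of digestive enzymes made by the exocrine pancreas rose from near 0, among them the carboxypeptidases cpb1 (153 ± 3.21 against 0.161 ± 0.0941 CPM) and cpa1 (233 ± 7.86 against 0.362 ± 0.187 CPM), the elastase cela1.5 (228 ± 3.996 against 0.253 ± 0.0969 CPM) and the chymotrypsin-like ctrl (152 ± 3.17 against 0.222 ± 0.152 CPM). The nuclease gene dnase1 had no count in WT control and was at least 379-fold higher with T3, and the forkhead factor foxo6 was 2344-fold (95% counting interval 420.2 to 92613, 1 count in the lower group) higher. Heat shock genes fell in the opposite direction, the chaperone hspa1b from 399.6 to 0.292 CPM (-10.38 ± 0.11) and hsp70 to 1.11 from 905 CPM (-9.68 ± 0.13), and hsp90aa1.2 was at least 1937-fold lower. For each of these genes 3 of 3 T3 libraries lay beyond every control library, which their choice required for all but thrb. The largest Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test was 3.8e-12. Near-identical copies of the hspa1, hsp30 and cela1 families can exchange reads, so values of single copies are uncertain.

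Among known thyroid hormone response genes, 12 of 16 measured members rose, 1 fell and 3 did not pass, with nfic at 2.83 ± 0.15 and the histone methyltransferase gene dot1l at 1.30 ± 0.07 among those that rose. Known thyroid hormone response genes calls adjusted over the list alone numbered 13, with a median log2 fold change of 0.93 (camera adjusted p = 8.8e-04, adjusted p = 0.0907 with an estimated correlation). The rise of klf9, an early response gene of T3 in amphibians, was 0.75 ± 0.26 (edgeR adjusted p = 0.02298, 3 of 3 libraries), and the log2FC of klf9, T3 effect, WT intestine, no longer passed without WT control replicate 1 (0.75, adjusted p = 0.0553), WT control replicate 3 (0.67, adjusted p = 0.0773), WT T3 replicate 1 (0.75, adjusted p = 0.0574) or WT T3 replicate 2 (0.74, adjusted p = 0.0532). Of MAPK feedback and immediate early genes, 3 of 37 measured members rose, 31 fell and 3 did not pass, led by fosl1 at -5.94 ± 0.12 and atf3 at -2.13 ± 0.08, both members of the AP-1 and ATF family, and 33 of the 37 were lower in TRDKO control too. MAPK feedback and immediate early genes had 34 calls adjusted over the list alone and a median log2 fold change of -0.90 (camera adjusted p = 5.1e-10). In the list of heat shock and oxidative stress, 4 of 36 measured members rose, 27 fell and 5 did not pass. Heat shock and oxidative stress calls adjusted over the list alone numbered 31, with a median log2 fold change of -0.99 (camera adjusted p = 3.2e-10). The summed level of that list was 17690 ± 242 CPM in WT control and 11849 ± 202 CPM in WT T3. Interferon response genes moved the other way, where 21 of 28 measured members rose, 2 fell and 5 did not pass, with the guanylate-binding protein gbp2 at 2.31 ± 0.09 and irf1 at 2.11 ± 0.05. Interferon response had 23 calls adjusted over the list alone and a median log2 fold change of 0.69 (camera adjusted p = 9.4e-06). For cholesterol synthesis, 2 of 26 measured members rose, 20 fell and 4 did not pass, including the LDL receptor gene ldlr at -2.12 ± 0.04. Cholesterol synthesis calls adjusted over the list alone numbered 22, with a median log2 fold change of -0.70 (camera adjusted p = 1.8e-07, adjusted p = 0.0773 with an estimated correlation).

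Markers of other cell types moved in WT intestine as well. For smooth muscle, 10 of 14 measured members rose, 0 fell and 4 did not pass, with lmod1 at 1.28 ± 0.06. Smooth muscle had 10 calls adjusted over the list alone and a median log2 fold change of 0.54 (camera adjusted p = 6.9e-04). For the exocrine pancreas, 17 of 20 measured members rose, 1 fell and 2 did not pass, and the summed level rose from 52.9 ± 0.862 to 1534 ± 10.98 CPM. Exocrine pancreas calls adjusted over the list alone numbered 18, with a median log2 fold change of 8.51, or 8.45 with 8 members held at the counting floor (camera adjusted p = 2.7e-09, adjusted p = 0.157 with an estimated correlation). For Hedgehog and BMP signalling, 20 of 35 measured members rose, 7 fell and 8 did not pass, with bmp4 at 2.09 ± 0.10 and foxl1, a factor of the subepithelial mesenchyme, at 1.86 ± 0.55. Hedgehog and BMP signalling had 28 calls adjusted over the list alone and a median log2 fold change of 0.60 (camera adjusted p = 0.0126, adjusted p = 0.248 with an estimated correlation). Several lists were not called as a whole. For fatty acid oxidation and lipid synthesis, 9 of 35 measured members rose, 15 fell and 11 did not pass. Fatty acid oxidation and lipid synthesis calls adjusted over the list alone numbered 25, with a median log2 fold change of -0.10 (camera adjusted p = 0.226). In the intestinal stem cell list, 9 of 20 measured members rose, 6 fell and 5 did not pass, with olfm4 at 1.68 ± 0.09 and the stem cell receptor lgr5 at -1.31 ± 0.18. Intestinal stem cell had 15 calls adjusted over the list alone and a median log2 fold change of 0.29 (camera adjusted p = 0.505). For apoptosis, 16 of 39 measured members rose, 11 fell and 12 did not pass, and for lymphocytes, 6 of 17 measured members rose, 2 fell and 9 did not pass. Apoptosis calls adjusted over the list alone numbered 27, with a median log2 fold change of 0.09 (camera adjusted p = 0.655). Lymphocytes had 8 calls adjusted over the list alone and a median log2 fold change of 0.09 (camera adjusted p = 0.447).

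With T3 in WT intestine, 9379 of 15491 genes tested passed, 4692 higher and 4687 lower, of which 960 and 979 changed at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). Higher calls were 50.03% of these, 57.1% with upper-quartile scaling and 54.8% with all libraries in 1 fit. Of the 39 lists 10 were called by camera, and 4 of the gene lists, T3 effect, WT intestine, kept the call with an estimated correlation.

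The next comparison asked which of these changes T3 made in intestine labelled TRDKO. The hormone-induced factor thibz rose by 7.28 ± 0.14 (27.3 ± 1.92 against 0.174 ± 0.0558 CPM) and foxo6 by 6.98 ± 0.21 (11.4 ± 0.988 against 0.0848 ± 0.0435 CPM). Among the largest rises were also hemopexin, hpx, by 6.84 ± 0.13 (78.6 ± 8.08 against 0.681 ± 0.139 CPM), avidin, avd, by 6.72 ± 0.18 (41.2 ± 6.15 against 0.383 ± 0.0125 CPM) and transferrin, tf, by 4.46 ± 0.07 (673 ± 60.7 against 30.6 ± 0.695 CPM). The pancreatic elastase cela2a fell by 5.81 on the log2 scale (3.66 ± 1.103 against 200.2 ± 9.08 CPM), the chymotrypsinogen ctrb1 changed by -5.67 ± 0.11 (4.72 ± 1.19 against 235 ± 5.804 CPM), the aquaporin aqp12a by -5.68 ± 0.14 and the claudin cldn18 by -5.65 ± 0.14. In each of these genes 3 of 3 T3 libraries lay beyond every control library, as their choice required (largest edgeR adjusted p, Benjamini-Hochberg, 4.3e-09).

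Known thyroid hormone response genes changed in the libraries labelled TRDKO too, where 13 of 16 measured members rose, 2 fell and 1 did not pass. Known thyroid hormone response genes calls adjusted over the list alone numbered 15, with a median log2 fold change of 0.87 (camera adjusted p = 2.9e-05). Both thrb at 2.83 ± 0.13 (32.9 ± 6.34 against 4.67 ± 0.338 CPM) and klf9 at 2.61 ± 0.29 (45.7 ± 21.3 against 7.56 ± 0.628 CPM) rose, and without intestine TRDKO T3 replicate 3 the log2FC of klf9, T3 effect, TRDKO intestine, was 2.94 and the log2FC of thra, T3 effect, TRDKO intestine, 1.41, while dio3, the deiodinase that inactivates the hormone, changed by -3.35 ± 0.25. The thra gene rose by 1.04 ± 0.32 (edgeR adjusted p = 0.0198, 2 of 3 T3 libraries above every control), and the log2FC of thra, T3 effect, TRDKO intestine, no longer passed without TRDKO T3 replicate 1 (0.91, adjusted p = 0.0756), TRDKO T3 replicate 2 (0.71, adjusted p = 0.117), TRDKO control replicate 1 (1.03, adjusted p = 0.06095) or TRDKO control replicate 3 (1.01, adjusted p = 0.0606), nor with limma-voom (0.87, adjusted p = 0.0866). For corticosteroid response, 9 of 14 measured members rose, 1 fell and 4 did not pass, with zbtb16, a glucocorticoid-induced zinc finger gene, at 2.33 ± 0.15. Corticosteroid response had 10 calls adjusted over the list alone and a median log2 fold change of 0.31 (camera adjusted p = 0.00109). For thyroid hormone metabolism and transport, 9 of 17 measured members rose, 3 fell and 5 did not pass, with the amino acid and hormone transporter slc7a5 at 3.82 ± 0.10 and the iodotyrosine deiodinase iyd at 1.82 ± 0.08. Thyroid hormone metabolism and transport calls adjusted over the list alone numbered 12, with a median log2 fold change of 0.59 (camera adjusted p = 0.02503, adjusted p = 0.107 with an estimated correlation). Mitosis genes rose together, as 43 of 45 measured members rose, 0 fell and 2 did not pass, with the spindle kinesin kif2c at 1.09 ± 0.12. Mitosis had 44 calls adjusted over the list alone and a median log2 fold change of 0.74 (camera adjusted p = 2.6e-19).

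Gut and organ markers divided in intestine labelled TRDKO. For the larval enterocyte, 29 of 38 measured members rose, 2 fell and 7 did not pass, with amn, which carries vitamin B12 uptake, at 1.91 ± 0.12 and apoa4 at 1.22 ± 0.08. Larval enterocyte calls adjusted over the list alone numbered 31, with a median log2 fold change of 0.42 (camera adjusted p = 1.0e-09, adjusted p = 0.0557 with an estimated correlation). For the exocrine pancreas, 0 of 20 measured members rose, 19 fell and 1 did not pass, and its summed level fell from 10146 ± 191 to 387 ± 33.8 CPM. Exocrine pancreas had 19 calls adjusted over the list alone and a median log2 fold change of -4.86, or -4.72 with 3 members held at the counting floor (camera adjusted p = 9.3e-24). For collagens and matrix proteins, 4 of 34 measured members rose, 22 fell and 8 did not pass, with the proteoglycan vcan at -1.15 ± 0.21 and col6a3 at -1.14 ± 0.08. Collagens and matrix proteins calls adjusted over the list alone numbered 27, with a median log2 fold change of -0.48 (camera adjusted p = 8.6e-07, adjusted p = 0.223 with an estimated correlation). For erythrocytes, 1 of 19 measured members rose, 11 fell and 7 did not pass, with hemgn at -2.27 ± 0.37. Erythrocytes had 13 calls adjusted over the list alone and a median log2 fold change of -0.61 (camera adjusted p = 9.6e-04). For endothelium, 2 of 24 measured members rose, 12 fell and 10 did not pass, and for lysosome and autophagy, 18 of 45 measured members rose, 3 fell and 24 did not pass. Endothelium calls adjusted over the list alone numbered 15, with a median log2 fold change of -0.33 (camera adjusted p = 0.0108, adjusted p = 0.382 with an estimated correlation). Lysosome and autophagy had 21 calls adjusted over the list alone and a median log2 fold change of 0.14 (camera adjusted p = 0.003403, adjusted p = 0.1904 with an estimated correlation).

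**Figure D2:**
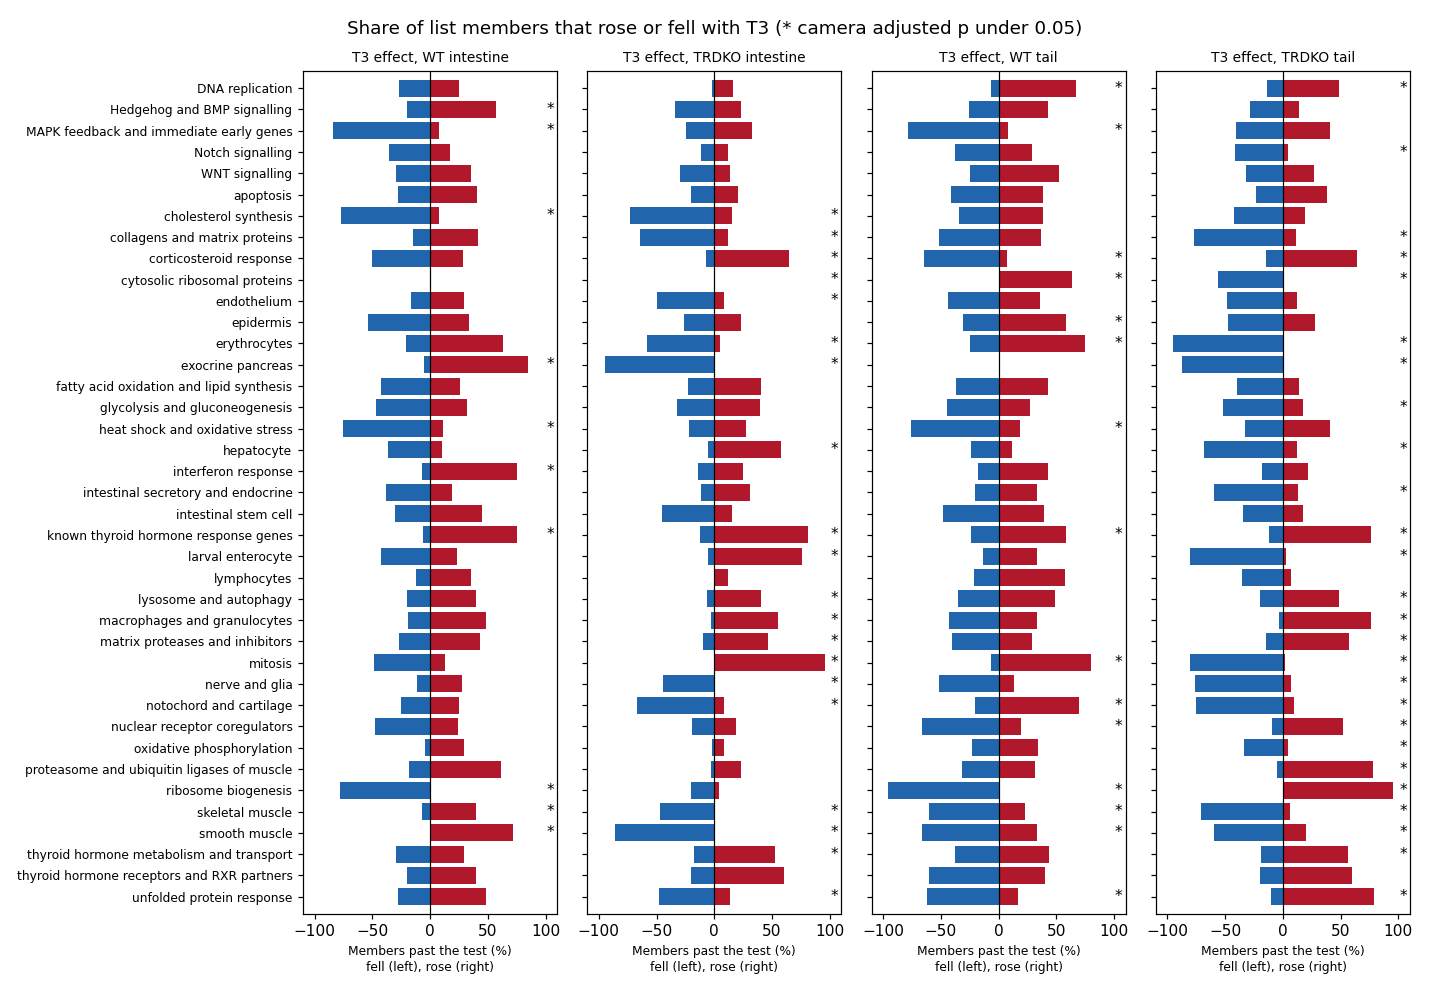
Percent of the measured members of each of the 39 gene lists that fell (bars to the left) or rose (bars to the right) with T3 in each genotype and organ, with a star at a camera adjusted p under 0.05 (preset correlation). In intestine labelled TRDKO 43 of 45 mitosis genes rose, and in WT tail 43 of 45 ribosome biogenesis genes fell.

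In total, 6343 of 15491 genes tested passed, 3194 higher and 3149 lower, of which 360 and 594 changed at least 2-fold (edgeR). Higher calls were 50.4%, and 47.0% with upper-quartile scaling. Without intestine TRDKO T3 replicate 3, the count for the T3 effect, TRDKO intestine, was 9004, and 21 lists were called against 20 with all libraries. The endothelium list was not called without it (camera adjusted p = 0.148).

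Intestine control libraries labelled TRDKO were then set against WT control. Pancreatic enzyme genes were far higher in TRDKO, cpb1 at 1142 ± 42.99 against 0.161 ± 0.0941 CPM (12.69 ± 0.16), the elastases cela1.1 at 679 ± 16.3 against 0.107 ± 0.0663 CPM (12.56 ± 0.13) and cela1.5 at 1300.5 ± 44.8 against 0.253 ± 0.0969 CPM, and dnase1 was at least 2124-fold higher. Heat shock genes were lower, hspa1b at 0.1799 ± 0.0739 against 399.6 ± 8.57 CPM (-11.04 ± 0.11), and hsp90aa1.2 was lower by 3171-fold (95% counting interval 877 to 26187, 2 counts in the lower group). The resistin-like gene retn.1 was lower, at -9.42 ± 0.10, and svep1l, with no count in TRDKO control, was at least 175-fold lower. All of these had 3 of 3 TRDKO libraries beyond every WT library, as their choice required (largest edgeR adjusted p, Benjamini-Hochberg, 7.5e-11). The thra difference was -0.94 ± 0.32 (edgeR adjusted p = 0.0236, 3 of 3 libraries), and the log2FC of thra, TRDKO against WT without T3, intestine, did not pass without TRDKO control replicate 1 (-0.93, adjusted p = 0.0641), TRDKO control replicate 3 (-0.91, adjusted p = 0.0643), WT control replicate 2 (-0.91, adjusted p = 0.0638) or WT control replicate 3 (-0.88, adjusted p = 0.06898).

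For the exocrine pancreas, 18 of 20 measured members were higher and 1 lower in TRDKO and 1 did not pass. Exocrine pancreas calls adjusted over the list alone numbered 19, with a median log2 fold change of 11.32, or 11.16 with 8 members held at the counting floor (camera adjusted p = 5.4e-12, adjusted p = 0.105 with an estimated correlation). For mitosis, 43 of 45 measured members were higher and 0 lower in TRDKO and 2 did not pass, with the cyclin ccnb3 at 2.15 ± 0.11 and the kinase plk1 at 1.51 ± 0.09. Mitosis had 43 calls adjusted over the list alone and a median log2 fold change of 0.99 (camera adjusted p = 2.1e-13). For heat shock and oxidative stress, 2 of 36 measured members were higher and 27 lower in TRDKO and 7 did not pass. Heat shock and oxidative stress calls adjusted over the list alone numbered 29, with a median log2 fold change of -0.71 (camera adjusted p = 2.6e-11). For MAPK feedback and immediate early genes, 0 of 37 measured members were higher and 33 lower in TRDKO and 4 did not pass, with fosl1 at -5.44 ± 0.12 and fosb at -3.04 ± 0.18. MAPK feedback and immediate early genes had 34 calls adjusted over the list alone and a median log2 fold change of -1.03 (camera adjusted p = 1.6e-14). For nerve and glia, 13 of 18 measured members were higher and 1 lower in TRDKO and 4 did not pass, with the neural crest factor sox10 at 2.63 ± 0.38 and the neuronal gene rbfox3 at 2.30 ± 0.22. Nerve and glia calls adjusted over the list alone numbered 16, with a median log2 fold change of 1.04 (camera adjusted p = 4.1e-04). For glycolysis and gluconeogenesis, 5 of 28 measured members were higher and 15 lower in TRDKO and 8 did not pass. Glycolysis and gluconeogenesis had 22 calls adjusted over the list alone and a median log2 fold change of -0.38 (camera adjusted p = 0.00509, adjusted p = 0.402 with an estimated correlation). Of the whole transcriptome, 8956 of 15491 genes tested passed, 4505 higher and 4451 lower, of which 1178 and 994 changed at least 2-fold (edgeR). Upper-quartile scaling moved the share of higher calls from 50.3% to 61.4%.

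The T3 effect was compared between genotypes as an interaction, the TRDKO effect minus the WT effect. In intestine the pancreatic enzyme genes had opposite effects, with differences of log2 fold changes of -14.66 ± 0.19 for cpb1, -14.62 ± 0.15 for cela1.1 and -14.50 ± 0.17 for cela1.5. Mean levels of cpb1 were 0.161 ± 0.0941 CPM in WT control, 153 ± 3.21 in WT T3, 1142 ± 42.99 in TRDKO control and 39.2 ± 5.46 in TRDKO T3. The plasma protein gene hpx had a difference of 14.01 ± 0.22, from 18.7 ± 0.924, 0.125 ± 0.0562, 0.681 ± 0.139 and 78.6 ± 8.08 CPM in the same order. Among response genes the T3 effect was lower in TRDKO for mmp11 (-5.49 ± 0.41) and thrb (-1.44 ± 0.20) and higher for klf9 (1.86 ± 0.39, edgeR adjusted p = 0.00131). Mean klf9 was 23.3, 39.1, 7.56 and 45.7 ± 21.3 CPM in the same order, so its difference carries the control levels. No difference passed for shh (-0.08 ± 0.08, adjusted p = 0.389) or dot1l (-0.23 ± 0.11, adjusted p = 0.0889).

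For the exocrine pancreas, 0 of 20 measured members had a higher and 19 a lower T3 effect in TRDKO and 1 did not pass. Exocrine pancreas calls adjusted over the list alone numbered 20, with a median difference of -13.25, or -12.95 with 8 members held at the counting floor (camera adjusted p = 1.0e-16, adjusted p = 0.0557 with an estimated correlation). For heat shock and oxidative stress, 23 of 36 measured members had a higher and 3 a lower T3 effect in TRDKO and 10 did not pass. Heat shock and oxidative stress had 28 calls adjusted over the list alone and a median difference of 1.21, or 1.22 with 2 members held at the counting floor (camera adjusted p = 5.6e-10). For mitosis, 37 of 45 measured members had a higher and 1 a lower T3 effect in TRDKO and 7 did not pass. Mitosis calls adjusted over the list alone numbered 40, with a median difference of 0.91 (camera adjusted p = 7.1e-10). For smooth muscle, 0 of 14 measured members had a higher and 12 a lower T3 effect in TRDKO and 2 did not pass. Smooth muscle had 12 calls adjusted over the list alone and a median difference of -1.18 (camera adjusted p = 1.4e-07). By edgeR, 8108 of 15491 genes tested passed, 4215 higher and 3893 lower, of which 1155 and 1434 changed at least 2-fold, and the genotype by T3 interaction, intestine, passed in 10560 genes without intestine TRDKO T3 replicate 3. The share of higher calls fell from 52.0% to 43.2% with upper-quartile scaling and to 46.2% with all libraries in 1 fit. The heat shock differences rest on levels of WT control intestine, where the list summed to 17690 ± 242 CPM against 10880 ± 174 in TRDKO control.

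In the WT tail, an organ that is resorbed at metamorphosis, T3 raised the annexin gene anxa1.3 by 8.29 ± 0.12 (63.1 ± 0.388 against 0.186 ± 0.0475 CPM) and thibz by 6.12 ± 0.12 (41.4 ± 3.68 against 0.558 ± 0.143 CPM). The globin hbg1 was 121-fold (95% counting interval 41.2 to 592, 3 counts in the lower group) higher. Stress genes fell, the chaperones hspa1b by 6.98 on the log2 scale (0.508 ± 0.131 against 64.8 ± 0.534 CPM) and hsp70 at -6.95 ± 0.07 (1.23 ± 0.278 against 153 ± 2.54 CPM), the AP-1 gene fosl1 at -6.86 ± 0.19 and the cystine transporter slc7a11 at -6.83 ± 0.06 (1.85 ± 0.3504 against 210.3 ± 5.11 CPM). Every T3 library (3 of 3) lay beyond every control library for these genes, as their choice required. Their largest adjusted p in edgeR was 2.3e-45. Among response genes, thrb rose from 7.68 to 57.8 CPM (2.88 ± 0.06) and dio3 by 2.08 ± 0.04. Falls were seen for thra (-0.96 ± 0.11), the gelatinase mmp9.1 (-1.16 ± 0.07) and klf9 (-0.90 ± 0.08). Control levels of klf9 were 17.2 CPM in WT and 1.68 in TRDKO.

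Of known thyroid hormone response genes, 10 of 17 measured members rose, 4 fell and 3 did not pass. Known thyroid hormone response genes calls adjusted over the list alone numbered 14, with a median log2 fold change of 0.45 (camera adjusted p = 0.0172, adjusted p = 0.0786 with an estimated correlation). For MAPK feedback and immediate early genes, 3 of 37 measured members rose, 29 fell and 5 did not pass. MAPK feedback and immediate early genes had 33 calls adjusted over the list alone and a median log2 fold change of -0.62 (camera adjusted p = 2.0e-09). For heat shock and oxidative stress, 7 of 37 measured members rose, 28 fell and 2 did not pass, and the summed level was 13344 ± 44.7 CPM in WT control and 7358 ± 3.18 CPM in WT T3. Heat shock and oxidative stress calls adjusted over the list alone numbered 36, with a median log2 fold change of -0.73 (camera adjusted p = 7.3e-11). For ribosome biogenesis, 0 of 45 measured members rose, 43 fell and 2 did not pass, with utp20 at -1.29 ± 0.08 and bop1 at -1.07 ± 0.07, and 45 of the 45 were lower in TRDKO control too. Ribosome biogenesis had 43 calls adjusted over the list alone and a median log2 fold change of -0.64 (camera adjusted p = 3.7e-12). For mitosis 37 of 46 measured members rose, 3 fell and 6 did not pass. For DNA replication 30 of 45 measured members rose, 3 fell and 12 did not pass, with the ribonucleotide reductase rrm2.2 at 1.74 ± 0.08. Mitosis calls adjusted over the list alone numbered 41, with a median log2 fold change of 0.76 (camera adjusted p = 4.6e-06). DNA replication had 33 calls adjusted over the list alone and a median log2 fold change of 0.43 (camera adjusted p = 0.002795). For nuclear receptor coregulators, 4 of 21 measured members rose, 14 fell and 3 did not pass, with nrip1 at -1.54 ± 0.05 and ncoa1 at -1.33 ± 0.07. Nuclear receptor coregulators calls adjusted over the list alone numbered 18, with a median log2 fold change of -0.30 (camera adjusted p = 0.001896, adjusted p = 0.0965 with an estimated correlation). For cytosolic ribosomal proteins, 45 of 71 measured members rose, 0 fell and 26 did not pass. Cytosolic ribosomal proteins had 41 calls adjusted over the list alone and a median log2 fold change of 0.07 (camera adjusted p = 0.00236, adjusted p = 0.743 with an estimated correlation).

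For skeletal muscle, 11 of 48 measured members rose, 29 fell and 8 did not pass, with the calcium release channel ryr1 at -1.56 ± 0.03 and the myosin myh4 at 1.32 ± 0.51. Skeletal muscle calls adjusted over the list alone numbered 40, with a median log2 fold change of -0.14 (camera adjusted p = 1.8e-04, adjusted p = 0.251 with an estimated correlation). In WT tail, 11723 of 17018 genes tested passed, 6029 higher and 5694 lower, of which 928 and 1012 changed at least 2-fold (edgeR), and 15 lists were called. Higher calls were 51.4%, and 57.6% with upper-quartile scaling. The WT control value rests on n = 2.

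In tail labelled TRDKO, T3 raised the collagenase mmp13l by 6.37 ± 0.18 (14.6 ± 0.546 against 0.1702 ± 0.0699 CPM), avd by 6.17 ± 0.20, thibz by 5.85 ± 0.12 (29.2 ± 1.28 against 0.5004 ± 0.104 CPM), olfm4 by 4.98 ± 0.14, the leptin gene lep by 4.21 ± 0.16 and klf9 by 3.37 ± 0.10 (17.6 ± 0.927 against 1.68 ± 0.308 CPM). Transcripts of absorptive gut epithelium, which summed higher in TRDKO control tail than in the other tail groups, fell. Among them, the bile acid binding protein fabp6 fell by 6.74 on the log2 scale (0.104 ± 0.04199 against 11.7 ± 0.859 CPM). The amino acid transporter slc6a19 was at -5.21 ± 0.10 (0.8098 ± 0.0922 against 30.2 ± 0.358 CPM), the galectin lgals4.1 at -4.80 ± 0.14 and enpp7 at -4.68 ± 0.23. T3 libraries lay beyond every control library in 3 of 3 cases for each gene, as their choice required, and the largest Benjamini-Hochberg adjusted p in edgeR was 4.5e-32. The receptor gene thrb rose by 0.96 ± 0.04 (54.4 ± 1.63 against 27.8 ± 1.32 CPM), thra by 0.47 ± 0.09 (edgeR adjusted p = 2.1e-06, and 0.173 for the log2FC of thra, T3 effect, TRDKO tail, with all 24 libraries in 1 fit) and the gelatinase mmp9.1 by 1.21 ± 0.04.

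Of known thyroid hormone response genes, 13 of 17 measured members rose, 2 fell and 2 did not pass. Known thyroid hormone response genes had 15 calls adjusted over the list alone and a median log2 fold change of 0.96 (camera adjusted p = 7.9e-10). For the larval enterocyte, 1 of 36 measured members rose, 29 fell and 6 did not pass, for the exocrine pancreas, 0 of 16 measured members rose, 14 fell and 2 did not pass, and for the hepatocyte list, 3 of 25 measured members rose, 17 fell and 5 did not pass. Larval enterocyte calls adjusted over the list alone numbered 30, with a median log2 fold change of -2.17, or -2.19 with 2 members held at the counting floor (camera adjusted p = 7.2e-15). Exocrine pancreas had 16 calls adjusted over the list alone and a median log2 fold change of -3.19 (camera adjusted p = 2.7e-12). Hepatocyte calls adjusted over the list alone numbered 20, with a median log2 fold change of -1.52 (camera adjusted p = 1.9e-04). The intestinal secretory and endocrine list also moved down, as 2 of 15 measured members rose, 9 fell and 4 did not pass, with tff3.3 at -3.95 ± 0.18. Intestinal secretory and endocrine had 12 calls adjusted over the list alone and a median log2 fold change of -0.42 (camera adjusted p = 0.0347, adjusted p = 0.0998 with an estimated correlation). For ribosome biogenesis, 43 of 45 measured members rose, 0 fell and 2 did not pass, with wdr75 at 1.08 ± 0.06 and utp4 at 0.96 ± 0.06. Ribosome biogenesis calls adjusted over the list alone numbered 43, with a median log2 fold change of 0.53 (camera adjusted p = 3.5e-20). For the unfolded protein response, 23 of 29 measured members rose, 3 fell and 3 did not pass, with hyou1 at 1.26 ± 0.08. Unfolded protein response had 26 calls adjusted over the list alone and a median log2 fold change of 0.28 (camera adjusted p = 4.6e-10). For proteasome and ubiquitin ligases of muscle, 32 of 41 measured members rose, 2 fell and 7 did not pass, with the muscle atrophy ligase fbxo32 at 1.90 ± 0.03. Proteasome and ubiquitin ligases of muscle calls adjusted over the list alone numbered 34, with a median log2 fold change of 0.14 (camera adjusted p = 8.5e-10). For matrix proteases and inhibitors, 20 of 35 measured members rose, 5 fell and 10 did not pass. Matrix proteases and inhibitors had 26 calls adjusted over the list alone and a median log2 fold change of 0.17 (camera adjusted p = 1.3e-04).

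For macrophages and granulocytes in the same tails, 23 of 30 measured members rose, 1 fell and 6 did not pass, with the phagocyte genes slc11a1 at 1.96 ± 0.37 and cybb at 1.35 ± 0.10. Macrophages and granulocytes calls adjusted over the list alone numbered 25, with a median log2 fold change of 0.33 (camera adjusted p = 1.3e-04). For notochord and cartilage, 2 of 20 measured members rose, 15 fell and 3 did not pass, with aggrecan, acan, at -0.68 ± 0.04. Notochord and cartilage had 17 calls adjusted over the list alone and a median log2 fold change of -0.29 (camera adjusted p = 6.0e-07). For oxidative phosphorylation, 2 of 47 measured members rose, 16 fell and 29 did not pass. Oxidative phosphorylation calls adjusted over the list alone numbered 18, with a median log2 fold change of -0.04 (camera adjusted p = 0.0488, adjusted p = 0.7603 with an estimated correlation). For Notch signalling, 1 of 24 measured members rose, 10 fell and 13 did not pass. Notch signalling had 11 calls adjusted over the list alone and a median log2 fold change of -0.17 (camera adjusted p = 0.0422, adjusted p = 0.113 with an estimated correlation). In all, 8999 of 17018 genes tested passed, 4543 higher and 4456 lower, of which 265 and 511 changed at least 2-fold (edgeR), and 26 lists were called. Upper-quartile scaling moved the share of higher calls from 50.5% to 39.8%.

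Between control tails, those labelled TRDKO held transcripts of liver, pancreas and gut that had no count in WT control. Albumin, alb, was at least 513-fold higher (27.5 ± 1.56 against 0 CPM), cpb1 at least 325-fold (17.4 ± 0.853 against 0 CPM), tm4sf4 at least 244-fold, cela1.1 at least 196-fold and the protease inhibitor serpina1 at least 174-fold. Stress genes were lower in TRDKO, slc7a11 at -8.08 ± 0.07 (0.779 ± 0.168 against 210.3 ± 5.11 CPM), hspa1b at -6.85 ± 0.09, hsp70 at -6.79 ± 0.07 and the heme oxygenase hmox1 at -6.13 ± 0.03 (32.6 ± 2.24 against 2276 ± 28.9 CPM). For these genes 3 of 3 TRDKO libraries lay beyond every WT library, as their choice required (largest edgeR adjusted p, Benjamini-Hochberg, 3.5e-40). Without hormone klf9 was lower in TRDKO, at -3.34 ± 0.11 (1.68 ± 0.308 against 17.2 ± 0.423 CPM) and thrb higher by 1.83 ± 0.07. The thra difference was -0.24 ± 0.10 (edgeR adjusted p = 0.0201, 2 of 3 libraries), and the log2FC of thra, TRDKO against WT without T3, tail, did not pass without TRDKO control replicate 2 (-0.15, adjusted p = 0.172), TRDKO control replicate 3 (-0.21, adjusted p = 0.0594) or WT control replicate 2 (-0.20, adjusted p = 0.101). The last leaves 1 WT control sample, assumed to vary like the other groups.

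For the larval enterocyte, 31 of 36 measured members were higher and 3 lower in TRDKO and 2 did not pass, and the summed level was 515 ± 8.63 CPM in TRDKO control tail and 152 ± 2.07 CPM in WT control tail. Larval enterocyte calls adjusted over the list alone numbered 34, with a median log2 fold change of 3.94, or 3.68 with 14 members held at the counting floor (camera adjusted p = 2.2e-08). For the exocrine pancreas, 14 of 16 measured members were higher and 0 lower in TRDKO and 2 did not pass. Exocrine pancreas had 14 calls adjusted over the list alone and a median log2 fold change of 8.41, or 6.03 with 10 members held at the counting floor (camera adjusted p = 6.6e-06). For the hepatocyte list, 20 of 25 measured members were higher and 4 lower in TRDKO and 1 did not pass, although its summed level was lower, at 941 ± 13.5 CPM in TRDKO control tail against 1364 ± 5.73 CPM in WT control tail. Hepatocyte calls adjusted over the list alone numbered 24, with a median log2 fold change of 2.16, or 2.17 with 10 members held at the counting floor (camera adjusted p = 0.00132). For mitosis, 45 of 46 measured members were higher and 1 lower in TRDKO and 0 did not pass, with the cyclins ccnb3 at 3.09 ± 0.08 and ccnb2 at 2.95 ± 0.20. Mitosis had 46 calls adjusted over the list alone and a median log2 fold change of 2.49 (camera adjusted p = 1.5e-21). For ribosome biogenesis, 0 of 45 measured members were higher and 45 lower in TRDKO and 0 did not pass. Ribosome biogenesis calls adjusted over the list alone numbered 45, with a median log2 fold change of -0.71 (camera adjusted p = 4.0e-13). For heat shock and oxidative stress, 3 of 37 measured members were higher and 33 lower in TRDKO and 1 did not pass. Heat shock and oxidative stress had 36 calls adjusted over the list alone and a median log2 fold change of -0.78 (camera adjusted p = 1.1e-12). By edgeR, 12435 of 17018 genes tested passed, 6201 higher and 6234 lower, of which 1586 and 1022 changed at least 2-fold. Upper-quartile scaling moved the share of higher calls from 49.9% to 56.8%.

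**Figure D3:**
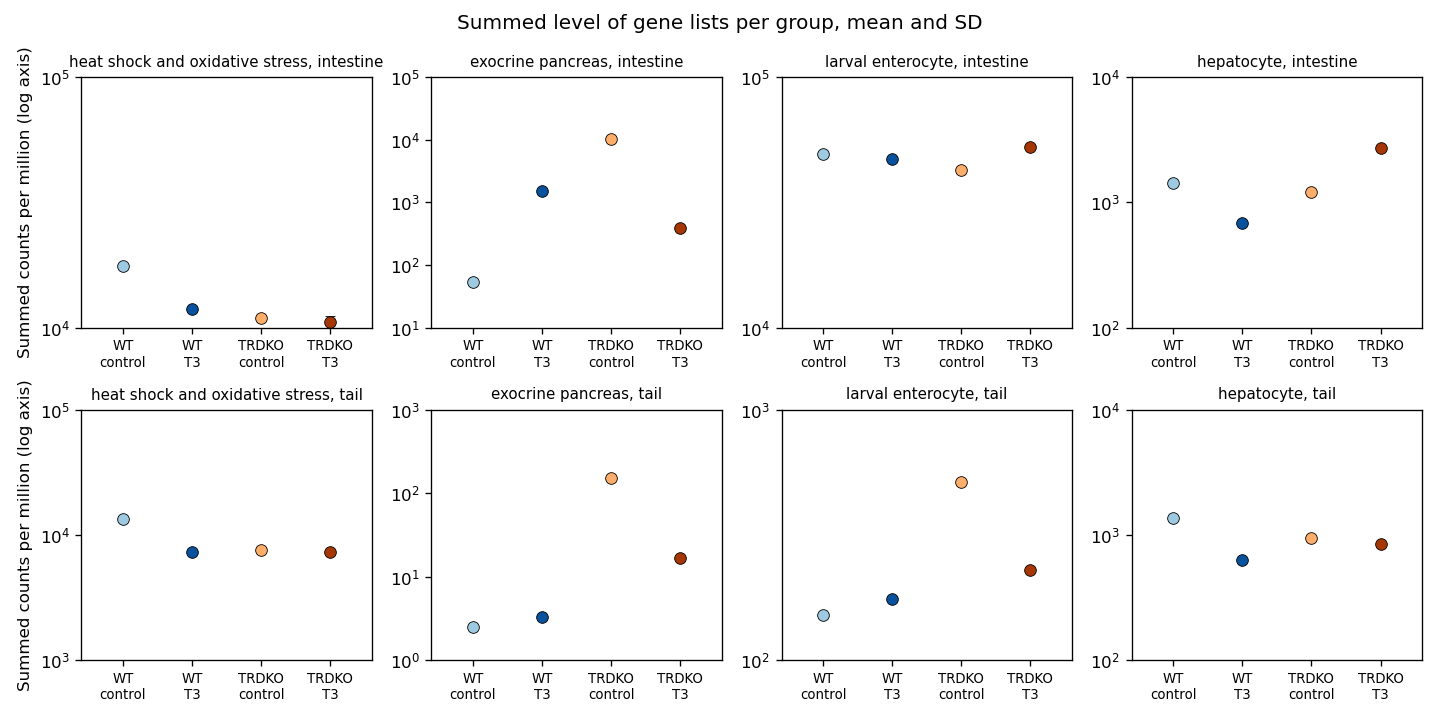
Summed CPM (log axes) of the heat shock and oxidative stress, exocrine pancreas, larval enterocyte and hepatocyte lists, as group mean (points) and SD (bars), intestine above and tail below. Exocrine pancreas genes summed to 10146 ± 191 CPM in TRDKO control intestine and 52.9 ± 0.862 CPM in WT control intestine.

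The genotype by T3 interaction in the tail asked the same question there. The T3 effect was higher in TRDKO for fosl1 by 9.13 ± 0.35, slc7a11 by 8.55 ± 0.23, hsp70 by 7.46 ± 0.25 and the epithelial gene olfm4 by 6.53 ± 0.29, and lower for the globin hba1 (-7.20 ± 0.23). Mean fosl1 levels were 19.5 ± 0.276 CPM in WT control, 0.164 ± 0.111 in WT T3, 0.397 ± 0.149 in TRDKO control and 1.96 ± 0.252 in TRDKO T3. Response genes differed in both directions, klf9 by 4.28 ± 0.13, mmp9.1 by 2.37 ± 0.08, thra by 1.43 ± 0.14, thrb by -1.92 ± 0.08 and mmp11 by -2.40 ± 0.20 (largest edgeR adjusted p, Benjamini-Hochberg, 4.0e-15). For ribosome biogenesis, 43 of 45 measured members had a higher and 0 a lower T3 effect in TRDKO and 2 did not pass. Ribosome biogenesis calls adjusted over the list alone numbered 43, with a median difference of 1.17 (camera adjusted p = 7.4e-19). For mitosis, 1 of 46 measured members had a higher and 42 a lower T3 effect in TRDKO and 3 did not pass. Mitosis had 43 calls adjusted over the list alone and a median difference of -0.98 (camera adjusted p = 6.7e-09). For the unfolded protein response, 21 of 29 measured members had a higher and 2 a lower T3 effect in TRDKO and 6 did not pass. Unfolded protein response calls adjusted over the list alone numbered 23, with a median difference of 0.69 (camera adjusted p = 1.2e-07). By edgeR, 11168 of 17018 genes tested passed, 5478 higher and 5690 lower, of which 1373 and 1389 changed at least 2-fold. Upper-quartile scaling moved the median log2 difference of all genes by -0.105 and the share of higher calls from 49.1% to 39.5%, and turned the median of no called list.

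The last tests asked whether T3 acted differently in the organs, as the tail effect minus the intestine effect. In WT the tail effect was higher for the vitamin D hydroxylase cyp24a1 by 6.09 ± 0.28, and lower for the detoxifying enzyme cyp1a1 (-7.26 ± 0.25). T3 effects on response genes were lower in the tail, mmp11 at -5.11 ± 0.42, klf9 at -1.71 ± 0.40, thrb at -1.43 ± 0.17 and shh at -0.93 ± 0.09 (largest edgeR adjusted p, Benjamini-Hochberg, 0.00262). Of known thyroid hormone response genes, 2 of 17 measured members had a higher and 11 a lower T3 effect in the tail and 4 did not pass. Known thyroid hormone response genes had 13 calls adjusted over the list alone and a median difference of -0.74 (camera adjusted p = 0.00453). For mitosis, 41 of 46 measured members had a higher and 0 a lower T3 effect in the tail and 5 did not pass, and for smooth muscle, 1 of 15 measured members had a higher and 12 a lower T3 effect in the tail and 2 did not pass. Mitosis calls adjusted over the list alone numbered 41, with a median difference of 0.89, or 0.90 with 1 member held at the counting floor (camera adjusted p = 8.2e-13). Smooth muscle had 13 calls adjusted over the list alone and a median difference of -0.76, or -0.73 with 1 member held at the counting floor (camera adjusted p = 3.9e-06). By edgeR, 7072 of 17887 genes tested passed, 3183 higher and 3889 lower, of which 926 and 1075 changed at least 2-fold. The share of higher calls was 45.0%, and 50.9% with size factors, 51.8% with upper-quartile scaling, 53.3% with the stricter filter and 54.2% with the 50 most abundant genes left out.

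Among libraries labelled TRDKO, the tail effect was higher for the gel-forming mucin muc5ac by 5.95 ± 0.15, for dio3 by 4.11 ± 0.21 and for mmp13l by 4.60 ± 0.61, and lower for fabp6 (-7.10 ± 0.37). The differences of thrb were -1.87 ± 0.13 and of shh -0.96 ± 0.09, while klf9 (0.76 ± 0.55, adjusted p = 0.343) and thra (-0.60 ± 0.39, adjusted p = 0.282) did not pass in edgeR. Without intestine TRDKO T3 replicate 3 the log2FC of klf9, tissue by T3 interaction, TRDKO, was 0.45 (adjusted p = 0.0101) and the log2FC of thra, tissue by T3 interaction, TRDKO, was -0.93 (adjusted p = 5.6e-07). For mitosis, 0 of 46 measured members had a higher and 43 a lower T3 effect in the tail and 3 did not pass, for the larval enterocyte, 1 of 39 measured members had a higher and 34 a lower T3 effect in the tail and 4 did not pass, and for ribosome biogenesis, 39 of 45 measured members had a higher and 0 a lower T3 effect in the tail and 6 did not pass. Mitosis calls adjusted over the list alone numbered 44, with a median difference of -0.999, or -1.002 with 1 member held at the counting floor (camera adjusted p = 3.4e-32). Larval enterocyte had 35 calls adjusted over the list alone and a median difference of -3.17, or -3.07 with 5 members held at the counting floor (camera adjusted p = 8.4e-26). Ribosome biogenesis calls adjusted over the list alone numbered 42, with a median difference of 0.64 (camera adjusted p = 1.0e-18). By edgeR, 5653 of 17887 genes tested passed, 3111 higher and 2542 lower, of which 615 and 729 changed at least 2-fold, and without that library 7529 genes passed. The share of higher calls was 55.0%, and 41.5% with size factors, 44.0% with no filter, 40.6% with the stricter filter, 41.0% with DESeq2 and 42.5% with the 50 most abundant genes left out.

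Genes that T3 changed in the same direction were compared between genotypes and organs, each pair using separate libraries. In intestine, WT and TRDKO shared 1274 against 967 expected higher and 1089 against 953 lower calls (Fisher's exact p = 1.0e-38 and 4.9e-09). In tail they shared fewer than expected, 1368 against 1609.5 higher and 1386 against 1491 lower (Fisher's exact p = 1.2e-18 and 1.0e-04). Among genes changed at least 2-fold they shared 50 against 14.5 higher and 38 against 30.4 lower (Fisher's exact p = 8.6e-15 and 0.154). Across genes, the correlation of log2 fold changes between genotypes was -0.195 in intestine (Spearman's rho 0.0201) and -0.107 in tail (rho -0.0977). Between organs, WT shared 2616 against 1629.5 expected higher and 2658 against 1533 lower (Fisher's exact p = 2.2e-290 and too small to compute). The correlation was 0.393 (rho 0.442). TRDKO shared 1305 against 883 and 1277 against 745 (Fisher's exact p = 4.3e-76 and 2.8e-129), with 0.276 (rho 0.224). The TRDKO difference without T3 shared 2465 against 1569 and 2453 against 1590 (correlation 0.476), so WT control levels may enter the WT overlap. Without intestine TRDKO T3 replicate 3 WT and TRDKO intestine shared 1413 higher and 1268 lower calls, and TRDKO intestine and tail 1846 and 1612. All 4 T3 effects pointed the same way in 293 higher and 209 lower genes against 97.8 and 77.6 expected, and at least 2-fold in 13 higher and 2 lower genes, thibz, foxo6, mmp11, nfic and iyd among the former and ch25h and cyp1b1 the latter, named after their values were seen.

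The T3 effect in WT and the TRDKO difference without T3 use the same WT control libraries. Their log2 fold changes correlated at 0.675 in intestine and 0.534 in tail across genes, beside 0.505 and 0.532 for 20 simulations of unchanged groups against those controls. The covariance was 0.802 against 0.0146 simulated in intestine and 0.516 against 0.0143 in tail. Both contrasts called 2545 genes higher and 2802 lower in intestine, where independent lists would share 1364 and 1347, and 4003 and 4115 in tail against 2197 and 2086. The simulations shared at most 0 genes per direction in intestine and 1 in tail. Of the 960 genes that T3 raised 2-fold in WT intestine 655 were higher in TRDKO control, and of the 979 that fell 725 were lower, as were 752 of 928 and 840 of 1012 in tail. The simulations hold no real deviation of the WT control group, and the controls cannot be split into parts of 2 libraries each. Part or all of the excess may therefore come from the shared controls.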

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

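Tests of the stress, hormone response and gut transcript patterns in this part were chosen after the result was seen. The interaction tests and the counts over other splits, except those within each organ, were planned.

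Stress genes stood high in the WT control libraries of both organs, where the list of heat shock and oxidative stress summed to 17690 ± 242 CPM in intestine and 13344 ± 44.7 CPM in tail, and lower in the other 3 groups of each organ. T3 alone as the cause is argued against, since without T3 the stress genes that fell 2-fold with T3 in WT were lower in TRDKO as well, with median log2 fold changes of -4.46 in intestine and -3.31 in tail (whole list -0.71 and -0.78). With the choosing and the compared WT control libraries kept apart the medians were -4.35 to -4.29 and -3.39 to -3.23. This removes the noise of single libraries but not a level common to that group. A single aberrant library is argued against too, because every WT control library lay above all other libraries for 100% of these genes in intestine and 87.5% in tail. Handling of the WT control animals may have raised them, as 14 of these genes were shared by both organs against 8 expected, but a state of that group and its handling cannot be told apart, and genotype and T3 acting together stay open, untested. Where this is so, T3 falls of these genes in WT and their interactions carry the level of that control group. So would T3 changes and interactions of klf9 in tail and of lists shifted alike with T3 in WT and in TRDKO control. Low in both were MAPK feedback and immediate early genes in intestine (31 and 33 of 37) and ribosome biogenesis in tail (43 and 45 of 45). Mitosis in tail was high in both (medians 0.76 and 2.49).

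Thyroid hormone response genes rose with T3 in libraries labelled TRDKO, with a rise of thibz equal to 59.1% of the WT T3 level in intestine and 67.7% in tail. Swapped genotype labels in the T3 groups are argued against in intestine, where the 9 genes present in both WT groups and nearly absent in TRDKO control (chosen within the organ, after a choice over both organs had left 1 gene) stood at a median of 0% of the WT T3 level in TRDKO T3. WT tissue mixed into those libraries is argued against there too, since the upper quartile of these genes was 0.256%. In tail only 4 such genes exist (0.164% and 0.651%), and genes of the reverse pattern stood in TRDKO T3 at a median of 46.1% of the TRDKO control level in intestine and 8.89% in tail, so in tail swapped labels and mixing cannot be told apart from a true response. Receptor-bearing siblings among the animals labelled TRDKO share the background and may lack the same genes, so they cannot be told apart from a response without these receptors, nor can residual receptor activity, which was not tested.

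Exocrine pancreas and gut transcripts differed between groups by large factors, the pancreas list from 52.9 ± 0.862 to 10146 ± 191 CPM between WT and TRDKO control intestine, where ctrc and cpa1 stood at 0.658 and 0.362 CPM in WT control and cpa1 at 1388 CPM in TRDKO control. Pancreas tissue taken with the intestine is a candidate source: the quartiles of the log2 fold changes lay apart by 0.690 for T3 in TRDKO, near 1 common factor, but 2.03 for T3 in WT, so dissection and regulation cannot be told apart. Intestine RNA carried into the tail TRDKO control libraries could account for gut transcripts there, but 1 carried share would put the lists at 1 percentage of their intestine level, and larval enterocyte genes stood at a median of 0.429% (quartiles 0.333% and 0.619%) and pancreas genes at 1.14% (0.885% and 1.26%), so this cannot be told apart from other sources, as the pancreas share of such tissue can vary. The hepatocyte list stood higher, at 18.8% (quartiles 2.02% and 40.5%), which goes against intestine RNA as the source of the liver transcripts, but over 4 genes, too few to exclude it. Of 36 enterocyte, 16 pancreas and 25 hepatocyte genes measured in tail, 11, 1 and 8 reached 1 CPM in WT control tail, and none of the lists shares a gene with another list.

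The T3 effect differed between genotypes in 8108 genes in intestine and 11168 in tail, and between organs in 7072 genes in WT and 5653 in TRDKO, by the interaction tests in edgeR. Of 100 splits of the intestine libraries only the real one gave as many interaction genes (highest other 1071). These splits put genotypes and treatments together in a group, so main effects widen the spread and lower the counts, and chance is not excluded by them. For the organ test in TRDKO 8 of 100 splits gave as many (highest other 12804), so these do not exclude chance, but splits that mix organs carry the difference between organs, a structure of the samples, and give no count without a change. Of 100 splits that kept each library in its organ only the real one gave as many (highest other 3998). As they mix T3 with control, which also widens the spread, they do not exclude chance either. For T3 in WT intestine, T3 in TRDKO intestine, TRDKO against WT intestine and T3 in TRDKO tail the 10 possible splits are too few for a share under 0.05, with real counts of 9379, 6343, 8956 and 8999 and a highest other of 0 in each.

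Opposite T3 effects in the genotypes in intestine singled out the following differences of log2 fold changes, TRDKO minus WT: cela1.1 -14.62, cela1.5 -14.50, cpb1 -14.66, ctrb1 -14.11, dio3 -7.48, hpx 14.01, mecom -1.86, noxo1.1 -7.60 and prmt1 0.89. The log2FC of dio3, genotype by T3 interaction, intestine, was -10.99 without WT control replicate 3 and -6.88 without replicate 1, and the log2FC of ctrb1, genotype by T3 interaction, intestine, -14.86 without WT control replicate 2 and -13.51 without replicate 3. Among lists the median differences were exocrine pancreas -13.25 (-12.95 with members at the counting floor), skeletal muscle -1.54 (-1.55 at the floor) and smooth muscle -1.18. In tail the differences were fosl1 9.13, hba1 -7.20, hsp70 7.46, hsp90aa1.2 -1.39, klf9 4.28, lep 5.58, mmp9.1 2.37, mmp9.2 2.50, noxo1.1 -4.52, olfm4 6.53, prmt1 1.57, slc7a11 8.55 and thra 1.43. Among lists in tail they were nuclear receptor coregulators 0.49, corticosteroid response 0.59, mitosis -0.98, unfolded protein response 0.69, cytosolic ribosomal proteins -0.13, ribosome biogenesis 1.17, notochord and cartilage -0.61 and erythrocytes -1.22 (-1.22 at the floor). With an estimated correlation the calls of exocrine pancreas in intestine (adjusted p = 0.0557) and cytosolic ribosomal proteins in tail (adjusted p = 0.637) were lost.

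Opposite T3 effects in the organs, tail minus intestine, singled out in WT klf9 -1.71, muc5ac 10.12 and olfm4 -3.28, with the list smooth muscle -0.76 (-0.73 with members at the counting floor). In TRDKO they were dio3 4.11, enpp7 -5.15, fabp6 -7.10, muc5ac 5.95 and shh -0.96, with the lists mitosis -0.999 (-1.002 with members at the counting floor), unfolded protein response 0.44, cytosolic ribosomal proteins -0.22, larval enterocyte -3.17 (-3.07 at the floor) and hepatocyte -2.16 (-2.17 at the floor). Without tail WT control replicates 1 and 3 the log2FC of muc5ac, tissue by T3 interaction, WT, was 9.44. All differences of genes named here passed the interaction test in edgeR, and those of lists passed camera with the preset correlation, where cytosolic ribosomal proteins in TRDKO lost the call with an estimated correlation (adjusted p = 0.728).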

How the results depend on the processing

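The alternatives named last in the processing section were chosen after the data were seen, and all others were planned. No result changed sign past its threshold. Of named-gene log2 fold changes under other settings 3630 stayed on their side of the threshold, 11 newly passed and 29 no longer passed, and with a library left out 2897 stayed, 6 newly passed and 73 no longer passed. Counts of genes with 1 library left out stayed within 1.5 times the reported count in all 80 cases. A 2-fold minimum, a stricter criterion by construction, left T3 effect, WT intestine 1939, T3 effect, TRDKO intestine 954, TRDKO against WT without T3, intestine 2172, genotype by T3 interaction, intestine 2589, T3 effect, WT tail 1940, T3 effect, TRDKO tail 776, TRDKO against WT without T3, tail 2608, genotype by T3 interaction, tail 2762, tissue by T3 interaction, WT 2001 and tissue by T3 interaction, TRDKO 1344 genes. With the stricter count filter, which tests fewer genes, the 2-fold counts were T3 effect, WT intestine, 2-fold 1048, T3 effect, TRDKO intestine, 2-fold 477, TRDKO against WT without T3, intestine, 2-fold 1010, genotype by T3 interaction, intestine, 2-fold 1430, T3 effect, WT tail, 2-fold 1117, T3 effect, TRDKO tail, 2-fold 251, TRDKO against WT without T3, tail, 2-fold 1311 and genotype by T3 interaction, tail, 2-fold 1659. With an estimated correlation the lists called numbered 4 for T3 effect, WT intestine, 7 for T3 effect, TRDKO intestine, 5 for TRDKO against WT without T3, intestine, 7 for genotype by T3 interaction, intestine, 6 for T3 effect, WT tail, 16 for T3 effect, TRDKO tail, 9 for TRDKO against WT without T3, tail, 10 for genotype by T3 interaction, tail, 5 for tissue by T3 interaction, WT and 7 for tissue by T3 interaction, TRDKO, and with fry, which tests whether genes of a list move 1 way and compares it with no other genes, 31 for T3 effect, WT intestine, 30 for TRDKO against WT without T3, intestine, 32 for genotype by T3 interaction, intestine, 30 for T3 effect, WT tail, 37 for TRDKO against WT without T3, tail, 35 for genotype by T3 interaction, tail, 31 for tissue by T3 interaction, WT and 28 for tissue by T3 interaction, TRDKO. At 2-fold in both contrasts the overlap of T3 calls was 111 higher and 90 lower in WT and TRDKO intestine, 50 higher and 38 lower in WT and TRDKO tail, 202 higher and 333 lower in WT intestine and WT tail and 56 higher and 84 lower in TRDKO intestine and TRDKO tail. The overlap of T3 calls, WT and TRDKO tail, higher, was 845 with DESeq2 against 1368, and the cause was not tested. The relation of the T3 effect in WT to the TRDKO effect without T3 had r = 0.749 in intestine and 0.693 in tail over genes past the threshold alone, against 0.675 and 0.534. With the replicate number as a block the counts were 9238, 6060, 8773, 7899, 11731, 8952, 12373, 11174, 6953 and 5264 in the order above, none beyond 1.5 times the reported count, and same-numbered samples did not deviate together, with a correlation over 0.1 in 0 of 18 pairs within intestine, 0 of 18 within tail and 0 of 12 across organs at 1 genotype and treatment (among other pairs intestine TRDKO T3 replicate 1 and tail TRDKO control replicate 1 reached 0.198), so the numbers do not pair the samples. Genes near the counting floor are limited by depth, since 3 counts over a group is the lowest level that could be told from 0.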

Other observations

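The tests of linkage to the receptor genes in this part were chosen after the result was seen, and the list tests were planned.

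Immune, WNT and epidermal genes were read in the tail without T3. Of interferon response genes in control tails 19 of 28 measured members were higher and 5 lower in TRDKO and 4 did not pass, with rsad2, an antiviral enzyme, at 2.19 ± 0.40. Interferon response calls adjusted over the list alone numbered 24, with a median log2 fold change of 0.52 (camera adjusted p = 0.0213, adjusted p = 0.123 with an estimated correlation). For WNT signalling, 31 of 44 measured members were higher and 8 lower in TRDKO and 5 did not pass, with the antagonist sfrp5 at 2.41 ± 0.51. WNT signalling had 40 calls adjusted over the list alone and a median log2 fold change of 0.45 (camera adjusted p = 3.8e-04, adjusted p = 0.0859 with an estimated correlation). For epidermis, 27 of 46 measured members were higher and 14 lower in TRDKO and 5 did not pass. Epidermis calls adjusted over the list alone numbered 41, with a median log2 fold change of 0.35 (camera adjusted p = 0.0214, adjusted p = 0.105 with an estimated correlation).

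Genes present in both WT groups and nearly absent in TRDKO control, 12 in all (57 showed the reverse) and including retn.1, svep1l, tap1 and nobox, may mark a difference of genetic background. Linkage to the targeted receptor genes is argued against for 11 of the 12, which lay on other chromosomes than 10 and 6, the carriers of thra and thrb. For LOC100496194 on chromosome 10, 7.58 Mb from thra and named after its values were seen, linkage cannot be told apart from another cause, as 1 gene of 12 (8.33%, exact 95% interval 0.211% to 38.5%) is too few to set against 14.2% of 13630 background genes. On chromosome 8, noticed afterwards, lay 7 of the 12.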
